A study of Anoectochilus roxburghii with 9 samples.

How the data were processed

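RNA was measured in 9 leaf libraries of Anoectochilus roxburghii, a medicinal orchid, as messenger RNA sequencing. Per the labels, the leaves had received a transient overexpression treatment and were taken 3 days later. The titles placed 3 libraries in an empty vector group (EV), 3 in an ArPHR2 overexpression group and 3 in an ArPHR4 overexpression group, each numbered 1 to 3. Per the labels' protocols, total RNA was extracted with a column kit and the libraries were made with a SMARTER mRNA-Seq kit. The read length, strand setting, assembler, aligner and counting tool are not given in the sources used here.

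The deposited table gives 85512 assembled genes, each with a count and an FPKM per library, per the file headers. The IDs have the form that the Trinity assembler writes for a transcriptome built without a genome, and the deposited files used here pair none of them with a gene name, a description or a position. The counts as deposited by the authors are whole numbers that sum to between 16032716 and 17244083 per library. The FPKM values deposited by the authors are fragments per kilobase of transcript scaled to sequencing depth. The gene length implied by count and FPKM differs between libraries for many genes, so the counts may come from an estimator that divides reads among transcripts of a gene and may have been rounded before deposit. A second deposited file held pairwise values between libraries of an unnamed measure and another held sample names; neither was used. No per-library column of the expression table was left out.

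The counts were tested with edgeR 4.0.16 in R 4.3.3. Of the 85512 genes, 12386 had no count in any library, and 27275 passed edgeR's expression filter by group and were tested. They held 99.4% to 99.6% of the counts of each library. Library sizes were scaled by TMM, and 1 quasi-likelihood model with 3 group means was fitted to the 9 libraries, which left 6 residual degrees of freedom. Benjamini-Hochberg adjustment was made over the tested genes, separately for each of the 3 comparisons, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F. CPM values are counts relative to the TMM-scaled library sizes. Where a group had 0 counts of a gene, the fold is a lower bound against 3 counts over the group's 3 libraries. Where it had 1 to 3 counts, the ratio has an exact (Clopper-Pearson) 95% interval that covers counting error only.

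The comparisons, tests, main alternatives and naming rule were fixed before the data were examined. The division of genes by abundance, the 100 most abundant genes, the top-ranked genes, the sets of genes seen in some groups, the separate overlap values for the more abundant genes and the analysis of implied length were chosen after seeing the data. The rule asked for the 2 IDs that rose most and the 2 that fell most in each comparison where no names were paired with IDs, among called genes with a mean of at least 1 CPM over all libraries and no overlap between the libraries of both groups. A set of 21 gene lists (phosphate starvation, flavonoid synthesis, symbiosis, defence, photosynthesis, markers of other leaf cell types and others) had been fixed as patterns on gene descriptions. None could be applied, because the table holds no descriptions, and no list was tested. For the same reason the transcripts of ArPHR2 and ArPHR4 were not looked up, so the labels were not checked against the overexpressed genes. IDs that differ only in their last number belong to 1 assembly component and can share reads: 10639 of the tested genes had such a sibling. Reads from overlapping or antisense transcripts cannot be told apart here, since the strand setting is not given.

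The labels do not say whether the 3 libraries of a group came from separate plants, so p-values measure only the spread between these libraries, which may be technical. Over pairs of libraries of 1 group, the median squared difference per gene was 2.03 to 3.23 times what counting noise gives, so no 2 libraries looked like 1 library deposited again. Between groups it was 10.0 to 23.0 times. The common biological coefficient of variation was 7.76%. The numbers of the libraries were not used to pair them.

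The edgeR step was tested on simulated data with 200 changed genes among 27275. With gene-wise spread, it recovered 54 of 66 genes changed 4-fold and 29 of 67 changed 1.5-fold for ArPHR2 against EV, 57 of 66 and 34 of 67 for ArPHR4 against EV, and 53 of 66 and 26 of 67 for ArPHR4 against ArPHR2, each with the right sign. The share of false calls in the same simulations was 13.0%, 10.9% and 7.2%, against 3.91%, 4.31% and 6.29% when the spread followed the fitted trend. In these simulations the adjusted p was thus somewhat optimistic for the comparisons against EV where genes differ in spread. For ArPHR4 against ArPHR2 there were 9 false calls with either spread. Each setting was simulated once, with 200 changed genes, while in the data 44.3% and 52.0% of the tested genes were called against EV. The simulated shares and recoveries need not hold with that many changed genes. Alternatives were DESeq2 1.42.0, other scalings, other filters, fits of 2 groups only, a replicate block, each library left out, a 2-fold minimum, and limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with a mean FPKM of at least 1. A few more were chosen after seeing the data: robust shrinkage, counts summed per assembly component, all libraries of 1 number left out, implied length as an offset, and another centring of implied length. Single values per library were compared with exact permutation tests, for which 3 libraries against 3 cannot give a p below 0.1.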

Results

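Leaves that carried an empty vector, an ArPHR2 construct or an ArPHR4 construct were profiled at 3 days, with 3 libraries per group. PHR proteins are MYB-type transcription factors known from other plants as regulators of the response to phosphate shortage. The design asked how leaf gene expression differed between each overexpression group and the empty vector. Total counts were 16488391 to 16547194 per EV library, 16529182 to 17244083 per ArPHR2 library and 16032716 to 16757000 per ArPHR4 library. Genes are given by their assembly IDs, which the files do not pair with names, functions or genome positions. The transcripts of ArPHR2 and ArPHR4 were therefore not looked up, and the levels of the constructs were not analysed here.

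The 3 groups were separated from each other far more than their own libraries were. On log2 CPM, libraries of the same group correlated across genes with r of 0.979 to 0.985. EV and ArPHR2 libraries correlated with r of 0.940 to 0.944, EV and ArPHR4 libraries with 0.927 to 0.929, and ArPHR2 and ArPHR4 libraries with 0.949 to 0.951. The first principal component held 47.0% of the variance and placed ArPHR2 (17.6 to 21.9) between EV (-89.5 to -87.6) and ArPHR4 (68.3 to 69.8). The second held 24.7% and set ArPHR2 (-66.2 to -66.0) apart from both EV (19.4 to 21.7) and ArPHR4 (44.7 to 45.8). On component 3, which held 5.52%, the ArPHR4 library numbered 3 stood apart at -50.6, with the others of its group on the positive side. The 100 most abundant genes of each library took 20.4% ± 0.127 of its counts in EV, 19.6% ± 0.383 in ArPHR2 and 18.3% ± 0.0771 in ArPHR4 (SD, n = 3). Neither overexpression group overlapped EV in this share (exact permutation test, two-sided p = 0.1 each, the smallest possible; 0.15 after Benjamini-Hochberg adjustment over 9 such tests).

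**Figure D1:**
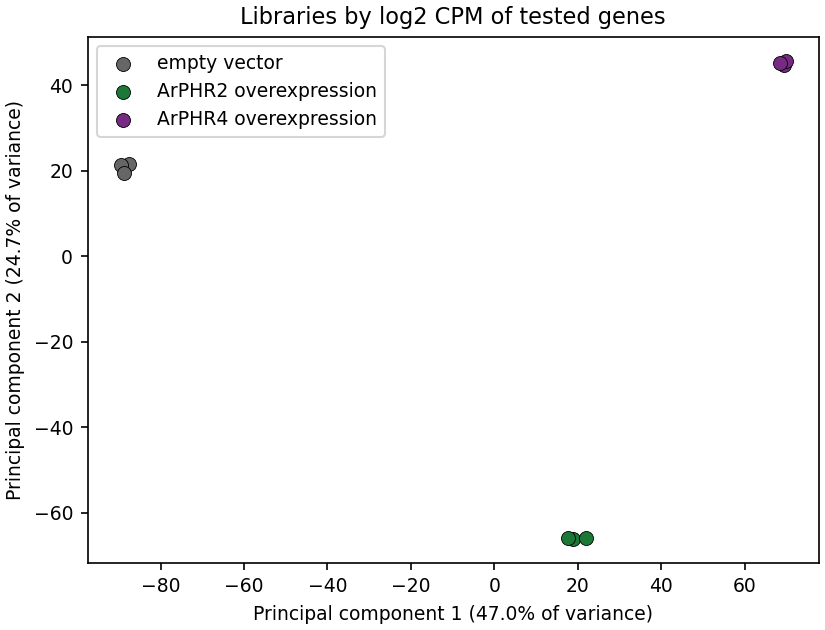
Each point is 1 library, placed by its scores on the first (47.0% of variance) and second (24.7%) principal components of log2 CPM over the 27275 tested genes; colours mark the 3 groups of 3 libraries. The EV libraries lie at -89.5 to -87.6 on the first component, ArPHR2 at 17.6 to 21.9 and ArPHR4 at 68.3 to 69.8.

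ArPHR2 leaves differed from EV leaves over a large part of the transcriptome. Of 27275 tested genes, 6157 rose and 5915 fell against EV, 44.3% of the total. With upper-quartile scaling 5981 rose and 6083 fell, and with limma on log2(FPKM + 1) 4444 rose and 3435 fell, so neither direction led throughout. Among called genes the median change was 0.63 on the log2 scale, and 2268 rose and 1412 fell by at least 2-fold. The gene with the highest level in EV leaves fell from 15997 ± 403 to 6642 ± 122 CPM (SD, n = 3), a log2 fold change of -1.27 ± 0.034 (SE, adjusted p = 9.1e-25, edgeR quasi-likelihood test). The third most abundant EV gene fell from 7041 ± 287 to 2114 ± 132 CPM. A gene at 955 ± 8.15 CPM in EV rose to 13443 ± 327 CPM and became the most abundant transcript of the ArPHR2 leaves (log2 fold change 3.82 ± 0.036, edgeR adjusted p = 1.95e-37). These 3 genes were chosen by their rank in abundance, after their values were seen.

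The largest increases were of genes with 0 counts in EV. TRINITY_DN64191_c0_g1 had 573 to 635 counts per ArPHR2 library (36.3 ± 3.06 CPM, SD, n = 3), which is at least 573-fold higher than EV (edgeR adjusted p = 1.89e-21). TRINITY_DN11276_c0_g1 reached 11.4 ± 0.187 CPM, at least 181-fold higher (edgeR adjusted p = 5.69e-16). Neither ID had a count in any ArPHR4 library. Among the decreases, TRINITY_DN3734_c1_g1 went from 2.97 ± 0.487 CPM in EV to 0 counts in ArPHR2, at least 50.4-fold lower (edgeR adjusted p = 1.53e-10). TRINITY_DN4682_c0_g3 went from 777 counts over the EV libraries to 3 over the ArPHR2 libraries, 278-fold lower (95% interval 94.7 to 1350; edgeR adjusted p = 2.27e-17). The last 2 IDs have sibling IDs in their assembly components, with which they can share reads.

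The direction of change in ArPHR2 leaves differed with abundance. The tested genes were divided by mean CPM into 4 bins of equal size. In bin 4, the most abundant, 2029 rose and 2846 fell. In the other bins more genes rose than fell, with 1968 against 1603 in bin 3, 1394 against 995 in bin 2, and 766 against 471 in bin 1. These numbers can include genes seen in 1 group alone, described below, of which there were 173 for ArPHR2 and 8 for EV. Their part in each bin was not counted. Called changes were smaller in abundant genes, with a median of 0.38 on the log2 scale in bin 4 and 2.00 in bin 1. In bin 1 low counts may have let only large changes be called, which was not tested. The direction in each bin held under both other scalings of the libraries. Of the 100 genes most abundant over all libraries, 44 rose and 44 fell. The limma fit on log2(FPKM + 1) called 7879 genes, of which 6920 were also called from the counts in the same direction.

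ArPHR4 leaves differed from EV leaves at more genes than ArPHR2 leaves did, with and without a fold limit. Against EV, 7120 genes rose and 7063 fell, 52.0% of those tested, and the median called change was 0.77 on the log2 scale. At least 2-fold changes numbered 2893 upward and 2597 downward, and at least 4-fold changes 1005 and 814, against 830 and 317 in ArPHR2. The 3 most abundant EV genes also fell here, to 7278 ± 283, 3873 ± 222 and 1846 ± 65.4 CPM (SD, n = 3). A gene at 3329 ± 163 CPM in EV and 6996 ± 238 CPM in ArPHR2 reached 12276 ± 220 CPM and was the most abundant transcript of the ArPHR4 leaves (log2 fold change against EV 1.88 ± 0.036, edgeR adjusted p = 5.67e-29). These genes too were chosen by abundance after their values were seen.

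Of the named IDs, TRINITY_DN9210_c1_g1 rose from 0 counts in EV to 4.87 ± 0.719 CPM in ArPHR4 (SD, n = 3), at least 76.8-fold (edgeR adjusted p = 1.97e-12). It had 7 counts over the 3 ArPHR2 libraries. TRINITY_DN6200_c0_g1 rose from 0 counts to 4.18 ± 1.14 CPM, at least 66.2-fold (edgeR adjusted p = 3.63e-11). TRINITY_DN12026_c0_g1 fell from 3.39 ± 0.367 CPM to 0 counts, at least 57.3-fold lower (edgeR adjusted p = 2.53e-09). TRINITY_DN33007_c0_g1 fell from 440 counts over the EV libraries to 1 over the ArPHR4 libraries, 470-fold lower (95% interval 83.8 to 18600; edgeR adjusted p = 2.56e-15), and had 6 counts over the ArPHR2 libraries.

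Among the 100 most abundant genes, 36 rose and 56 fell in ArPHR4 against EV, with 10 rising and 22 falling by at least 2-fold. In bin 4 by mean CPM, 2075 rose and 3097 fell, while in bin 3 2473 rose and 1571 fell; both orders held under the other scalings. In bin 2 the split was 1712 against 1468, and it became even with upper-quartile scaling, 1582 against 1582. In bin 1 it was 860 against 927. The share of rising genes among all calls was 50.2%, and it moved both ways with the processing: 44.9% (6406 rose and 7868 fell) with upper-quartile scaling of the counts, 49.2% with DESeq2 and 60.9% with limma on log2(FPKM + 1).

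**Figure D2:**
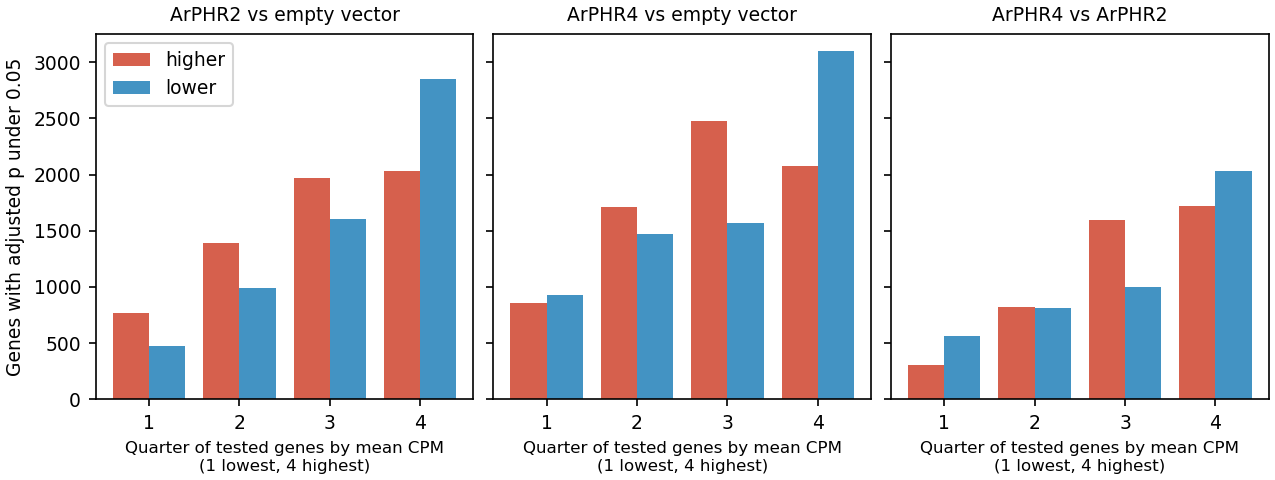
Bars give the number of genes (vertical axis) called higher (red) or lower (blue) at an edgeR adjusted p under 0.05 in each of 4 bins of the tested genes by mean CPM over all libraries (horizontal axis, 1 lowest to 4 highest), with 1 panel per comparison. In bin 4 more genes were lower than higher in each panel: 2846 against 2029, 3097 against 2075, and 2030 against 1723.

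ArPHR4 and ArPHR2 leaves also differed from each other. In the direct comparison, 4446 genes were higher and 4418 lower in ArPHR4, 32.5% of those tested, with 1063 and 1272 at 2-fold or more. The share higher in ArPHR4 was 50.2% of the calls, against 41.4% (3683 higher and 5203 lower) with upper-quartile scaling and 59.7% of 4944 calls with limma on log2(FPKM + 1). Of the 100 most abundant genes, 22 were higher and 66 lower in ArPHR4, and 0 and 5 of these passed 2-fold. The most abundant transcript of the ArPHR2 leaves was at 10440 ± 251 CPM in ArPHR4 (SD, n = 3; log2 difference -0.36 ± 0.032, edgeR adjusted p = 3.87e-11). The most abundant transcript of the ArPHR4 leaves was 0.81 ± 0.035 higher there on the log2 scale than in ArPHR2 (edgeR adjusted p = 1.01e-18).

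The largest differences between the constructs were of genes seen in 1 of the 2 groups. TRINITY_DN56295_c0_g1 had 240 to 268 counts per ArPHR4 library, and 1 count over the ArPHR2 and 2 over the EV libraries; it was 771-fold higher in ArPHR4 than in ArPHR2 (95% interval 138 to 30500; edgeR adjusted p = 1.45e-18). TRINITY_DN3393_c0_g2, which has a sibling ID, was at 3.50 ± 0.537 CPM in ArPHR4 (SD, n = 3) and had 0 counts in the other groups, at least 59.3-fold higher than ArPHR2 (edgeR adjusted p = 7.32e-10). TRINITY_DN64191_c0_g1 was at least 611-fold lower in ArPHR4 than in ArPHR2 (edgeR adjusted p = 2.6e-21). TRINITY_DN11574_c0_g2, which also has a sibling ID, had 213 to 256 counts per ArPHR2 library, and was at 1.01 ± 0.237 CPM in EV (SD, n = 3) and 0 counts in ArPHR4, at least 236-fold lower in ArPHR4 than in ArPHR2 (edgeR adjusted p = 7.26e-18).

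**Figure D3:**
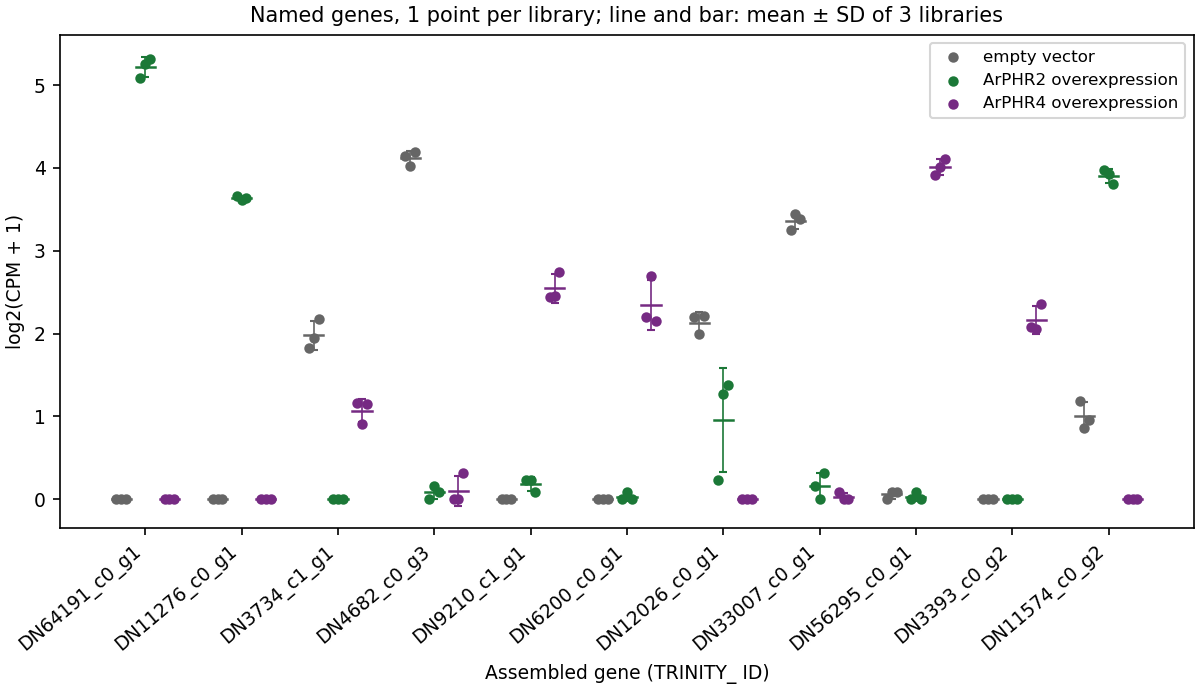
Each point is log2(CPM + 1) (vertical axis) of 1 library for the 11 IDs named by the fixed rule (horizontal axis); colours mark the 3 groups, and lines and bars give the mean and SD of 3 libraries. TRINITY_DN64191_c0_g1 and TRINITY_DN11276_c0_g1 have counts in the ArPHR2 libraries alone, and TRINITY_DN3393_c0_g2 in the ArPHR4 libraries alone.

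The responses to the constructs overlapped. Of the genes called against EV, 4461 rose and 4421 fell under both constructs, and 418 moved in opposite directions. Independent lists of the same sizes would share 1607 rising and 1532 falling genes, with 3138 in opposite directions. With no effect at all but the same EV libraries, 20 simulations gave at most 3 genes called in both with the same sign. Few genes can be called where nothing changes, so that count does not measure how far the responses were shared. The fold changes correlated across genes with r = 0.57, against a simulated mean of 0.51. Their covariance was 0.68, against 0.049 in the simulations, a difference of 0.64. Over the 13638 genes with the highest mean CPM, r was 0.80 against 0.50 simulated, and the covariance 0.41 against 0.0064. The simulations drew each library separately from the spread between libraries, so they hold no deviation common to the 3 EV libraries. These are too few to divide, so an unknown part of the overlap may come from them. With limma on log2(FPKM + 1), 5679 genes moved the same way under both constructs.

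Most genes that differed from EV in the same direction in both groups were not called between the constructs. Where a direct call did separate them, the change was more often the larger in ArPHR4. The levels of the constructs were not analysed, and the labels do not say whether the libraries came from separate plants. This order may therefore not reflect the factors themselves. Of the 8882 shared genes, 2675 that rose and 2730 that fell had no call between the constructs. Their median log2 fold changes in ArPHR2 and ArPHR4 were 0.76 and 0.79 for rising genes, and -0.57 and -0.59 for falling genes. A missing call does not show equal changes. By the direct test 2539 genes (28.6%) were further from EV in ArPHR4 and 938 (10.6%) were further in ArPHR2, a ratio of 2.71. The ratio stayed between 2.41 and 6.27 over the 26 settings examined. The 1310 genes that rose further in ArPHR4 had a median log2 fold change of 1.34 there and 0.70 in ArPHR2, and the 1229 that fell further had -0.93 and -0.50. A direct call also separated 1393 genes that rose and 1267 that fell in ArPHR4 but were not called in ArPHR2, and 830 that rose and 732 that fell in ArPHR2 but were not called in ArPHR4.

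**Figure D4:**
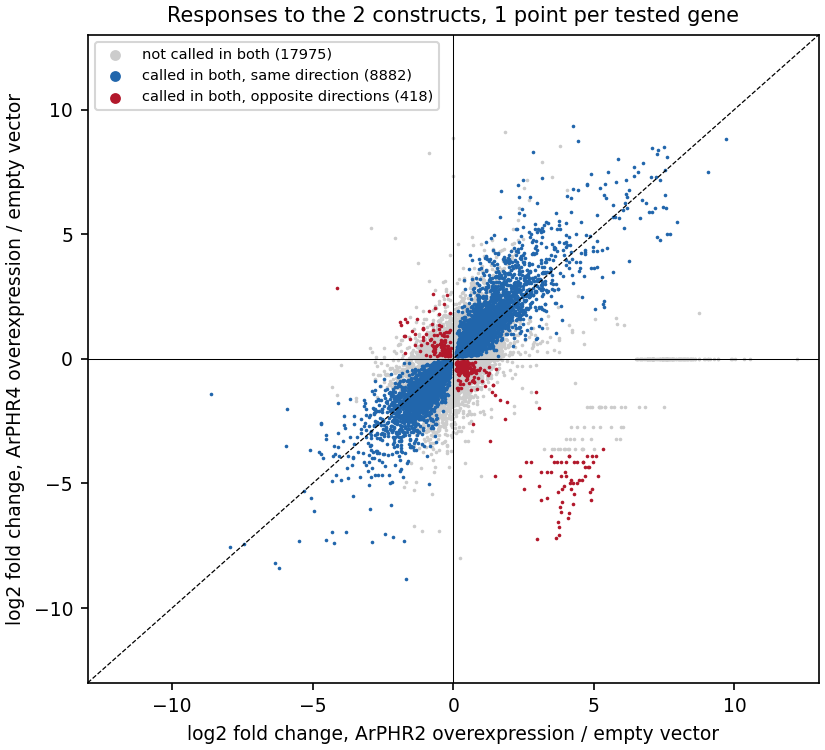
Each point is 1 of the 27275 tested genes, with its log2 fold change against EV in ArPHR2 (horizontal axis) and ArPHR4 (vertical axis) leaves; the dashed line marks equal changes. The 8882 genes called in both with the same sign (blue) lie along the dashed line, the 418 with opposite signs (red) include a group high in ArPHR2 and low in ArPHR4, and grey points were not called in both.

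Some genes were seen in 1 group alone, here meaning at least 10 counts in each of its libraries and at most 3 counts over the libraries of each other group. There were 173 such genes for ArPHR2, 7 for ArPHR4 and 8 for EV. A further 19 were seen in both overexpression groups and not in EV, and 6 in EV and ArPHR2 and not in ArPHR4. TRINITY_DN3734_c1_g1 was the gene seen in EV and ArPHR4 and not in ArPHR2. With a minimum of 5 counts the ArPHR2 set held 336 genes and the ArPHR4 set 30, and with a minimum of 20 counts 78 and 4.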

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

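The analysis of implied gene length in this part and its 2 centrings were chosen after the data had been seen. A set of 418 genes stood out because the 2 constructs moved them in opposite directions against EV. All of them also passed the direct test of the difference (edgeR, adjusted p under 0.05). That pass adds little, since opposite changes against the same EV libraries add up in the direct comparison. Independent lists of the same sizes would give 3138 such genes, more than were found. Of the 418 genes, 269 rose in ArPHR2 and fell in ArPHR4, with median log2 fold changes of 0.40 and -0.43. The other 149 fell in ArPHR2 and rose in ArPHR4, with -0.34 and 0.41. The count was 82 at 2-fold or more, 165 with limma on log2(FPKM + 1), 260 with implied length as an offset, and 267 without the libraries numbered 1.

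A signal outside the main measurement lay in the FPKM columns. Count divided by FPKM gives each gene an implied length per library, which moves when the transcripts of a gene change their shares or their effective lengths. Among 11468 genes with at least 100 counts and an FPKM of at least 5 in every library, limma called a shift of at least 1.5-fold in 56 genes for ArPHR2 against EV (31 longer, 25 shorter), in 98 for ArPHR4 against EV (42 longer, 56 shorter) and in 6 for ArPHR4 against ArPHR2. Without the fold limit it called 5808, 6863 and 1246 genes. Centring on each library's median left a median shift of 0.0364 and 0.054 on the log2 scale against EV, and with centring on gene-wise differences the calls fell to 3320, 3167 and 311. The 1.5-fold counts were then 53, 116 and 3, but the directions moved, to 21 longer and 32 shorter in ArPHR2 and 27 longer and 89 shorter in ArPHR4. The median spread within a group was 0.033 on the log2 scale, and the same step recovered 197 of 200 genes shifted 2-fold in simulated data with 0 false calls. A 2-fold shift lies far above that spread, so near full recovery was to be foreseen. The simulated data held no offset of whole libraries or of short genes, so they do not bear on the directions that moved with the centring. For each of the 3 comparisons 1 of the 10 splits of the 6 libraries, the real one, gave as many genes, with 0 genes in the highest other split. The other splits mix both groups on each side, so the group difference becomes spread and the 0 is no reference without an effect. In addition, 10 splits are too few for a share under 0.05.

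A fragment length that differed between libraries changes the effective length of short transcripts most. As the cause of the 98 larger shifts in ArPHR4 as a set it was argued against, since 57 of those genes (58.2%) had an implied length over 1000 bases. This share was near the 63.8% of all genes examined. The argument does not cover the shorter genes among the 98, and the 56 larger shifts in ArPHR2 were not checked in this way. For the small shifts a differing fragment length is a candidate explanation in ArPHR2. There, with gene-wise centring, 86.9% of the genes called under 1000 bases were longer, 228 of 230 among those under 300 bases. The median shift fell from 0.157 under 300 bases to -0.0187 over 2000. In ArPHR4 this explanation stays open, with 66.2% longer, 57 of 62 among those under 300 bases, and medians of 0.0784 and -0.00709. Reassignment of reads between similar transcripts by the authors' quantification, which is not described in the sources used here, may give such shifts too, and a change in transcript use under the constructs, which the design names, was not tested.

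Calls between the groups were set against other splits of the same 6 libraries. In ArPHR2 against EV 1 of 10 splits, the real one, gave as many calls (12072, against 0 in the highest other split). In ArPHR4 against EV it was 1 of 10 (14183 against 0), and in ArPHR4 against ArPHR2 1 of 10 (8864 against 0). These 10 splits are too few for a share under 0.05. Every other split also mixes both groups on each side, which turns the group difference into spread. The 0 calls there are therefore no reference for data without an effect.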

How the results depend on the processing

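The 3 counts of called genes and the count of genes moved the same way by both constructs stayed within 1.5 times in 90 of 100 alternative values, and no named gene reversed; the split of calls into higher and lower did depend on scaling. The others came from a 2-fold minimum or from limma on FPKM, which changes the unit, test, scaling and genes tested together. With a 2-fold minimum the calls were 3680 for ArPHR2 against EV, 5490 for ArPHR4 against EV, 2335 for ArPHR4 against ArPHR2 and 2411 shared, by construction. With limma on log2(FPKM + 1) they were 7879 for ArPHR2 against EV, 4944 for ArPHR4 against ArPHR2 and 5679 shared, and with a pseudocount of 0.1 they were 7947, 4864 and 5706; ArPHR4 against EV gave 10287 and 10306. The cause was not tested. The share of rising genes in the log2(FPKM + 1) fit was 60.9% for ArPHR4 against EV and 59.7% for ArPHR4 against ArPHR2, against 50.2% in both from the counts; upper-quartile scaling gave 44.9% and 41.4%. Leaving out each library in turn gave 10709 to 12410 calls for ArPHR2 against EV, 12904 to 14564 for ArPHR4 against EV, 7580 to 8805 between the constructs and 7768 to 8578 shared. The replicate block gave 12007, 14101 and 8779 calls and 8845 shared genes. Libraries with the same number are not paired by the labels. The correlations of their deviations from the group means were weak, -0.0029 to 0.036 with 8 of 9 above 0 and none over the limit of 0.1 for pairing. Pairs of different numbers gave -0.051 to 0.030, with 7 of 18 above 0. Of the 9 libraries, 5 correlated best with one of their own number. DESeq2 called 11421, 13561 and 8193 genes, of which 11414, 13547 and 8180 were also called by edgeR in the same direction. The median of all fold changes moved by at most 0.0515 under the scalings. Without all libraries numbered 3, the calls were 10557, 12461 and 7508; without those numbered 1 they were 9804, 12001 and 6687, and without those numbered 2 they were 9825, 11907 and 6553. Each of the 12 named results kept its sign and call in all 23 alternative settings that tested it (276 values over the 12 results), with a highest adjusted p of 0.00503 across edgeR, DESeq2 and limma. Sizes that rest on 1 to 3 counts in a group moved with single libraries. Without ArPHR2 library 2, TRINITY_DN56295_c0_g1 between the constructs went from a log2 fold change of 9.12 to 10.96. TRINITY_DN4682_c0_g3 in ArPHR2 against EV then went from -7.94 to -8.77. Without ArPHR4 library 1, TRINITY_DN33007_c0_g1 in ArPHR4 against EV went from -8.41 to -10.25. Of 498 other alternative values 22 were counted as moved by over 1.5 times, 9 of them under the 2-fold minimum and 6 with FPKM. These 498 include the 276 named values, which were judged by sign and call and not by size. With limma on log2(FPKM + 1), the log2 fold change of TRINITY_DN64191_c0_g1 in ArPHR2 against EV was 4.72, against 12.23 in the main fit. The other settings for gene lists were not run, because no list could be applied. Fewer of the low genes were called: of the 4 abundance bins, bin 1 had 18.1% of its genes called in ArPHR2 against EV, and bin 4 had 71.5%. Depth may limit the low genes, but this was not tested.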

Other observations

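The tests of a single source, of an ArPHR2-only source, of siblings, of the depth of the ArPHR2 libraries, of a step shared by the libraries numbered 3 and of their depth were chosen after the values had been seen, as were the fits without all libraries of 1 number. The 173 genes seen in ArPHR2 leaves alone held 6088, 5984 and 6248 counts in the 3 ArPHR2 libraries, 62 counts over the EV libraries and 3 over the ArPHR4 libraries. Of these genes, 112 were the only ID of their assembly component. The 19 genes seen in both overexpression groups but not in EV held 631 to 765 counts per ArPHR2 library, 853 to 863 per ArPHR4 library and 5 to 11 per EV library.

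For the excess of ArPHR2-only genes (173, against 7 for ArPHR4 and 8 for EV), depth was argued against by the library totals, since the summed ArPHR2 total was at most 1.03 times that of another group, where at least 10 counts in each library against at most 3 over a group would need 10 times. Trading of reads within a component was argued against for the 61 genes with a sibling, since in 4.92% of them (95% exact interval 1.03% to 13.7%) the siblings together lost at least 0.5 of what the gene gained; copies of the other 112 genes were not searched. An outside source held by EV and ArPHR2 in a single ratio was tested over 255 genes, which include all 173. They had at least 10 counts in each ArPHR2 library and at most 3 over ArPHR4. The ratio varied by 14.9 times counting noise, against at most 2.11 between ArPHR2 libraries, a spread that the minimum in each library lowers. No EV count was found for 136 genes, where counting would leave 19.8. These values argue against such a source for all 255 genes together. They do not decide for the 173, which were chosen for at most 3 EV counts, since a source for those alone among other genes would give such values too. Over the 189 genes with more than 60 ArPHR2 counts the ratio varied by 15.3 times (against 5.8), and by 13.4 times (against 3.98) over the 97 of these with EV counts. Among those 97 genes 4 had a ratio over 20%, while the quartiles were 2.83% and 6.43%. Their median squared deviation was 2.45 times counting noise. Neither the 13.4 nor the 2.45 decides for the bulk of the 97 genes, since they were kept for having EV counts. An outside source in the ArPHR2 libraries alone, where the 173 genes held 0.0362% of the counts, stays open because no sequences or names were at hand, and so does activation by ArPHR2, which the design names and which was not tested.

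The library numbered 3 lay lowest of its group on principal component 3 (5.52% of variance) in every group, at -7.93 in EV, -17.5 in ArPHR2 and -50.6 in ArPHR4, and a small set of genes stood highest in it. Of the 27 ways to take 1 library per group, number 3 throughout gave the most genes that exceeded both other libraries by over 1 log2 unit in each group, 12 against 3 in the next, and these held 738, 3876 and 5243 counts in the EV, ArPHR2 and ArPHR4 libraries numbered 3 and 114 to 479 counts in each of the others. Deeper sequencing was argued against, since library 3 had the lowest total in every group. The genes were also picked on log2 CPM, which is already scaled to depth. A processing step shared by these libraries may be behind the pattern but was not tested apart from it, since the count of 12 only restates it and the labels give no batch, and no biological explanation was tested. Of the 12 genes, 5 were called in ArPHR2 against EV, 8 in ArPHR4 against EV and 1 between the constructs.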
